A study of Mus musculus with 6 samples.

How the data were processed

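The series measured messenger RNA in pro-B cells, the B lineage precursors that assemble the immunoglobulin heavy chain gene, sorted by flow cytometry from adult C57BL/6 mouse bone marrow. There were 3 mice carrying floxed Skiv2l alleles together with a Cd79a-Cre driver (Skiv2l-deleted) and 3 mice with floxed Skiv2l alleles for which the labels name no Cre (control), with 1 library per mouse. RNA was purified on silica columns and made into strand-specific libraries, per the labels' protocols. The surface markers of the sort, the read length and the sex of the mice are not given in the sources used here.

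The authors deposited, for each mouse, 1 table of genes with FPKM and TPM (2 measures of expression scaled to transcript length and library size) and the mean coverage of each gene, per the file headers. The genome build was GRCm38, per the submitters' processing notes. The aligner, the quantification tool, its settings and whether it used strand are not given in the sources used here, so antisense and overlapping genes are uncertain. Each table listed 54752 gene identifiers. All but 29 of them were found in the GENCODE annotation used here, 53861 of them with the same version. The coordinates were identical in 100% of those 53861 and were not compared for the others. Between 7 and 9 identifiers per table stood on several lines, and their values were summed. The 37 mitochondrial genes were listed at 0 in all 6 libraries. By contrast, 5 nuclear copies of mitochondrial sequence took 3.23% to 4.37% of the FPKM in controls and 2.01% to 2.99% in Skiv2l-deleted libraries. A value of 0 below is therefore a value as listed and does not show that a transcript was absent.

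The tables hold no read counts. Within each library the ratio of FPKM to coverage was constant in single-transcript genes, which by the definitions of these deposited units corresponds to 1.74 to 2.40 Gb of aligned bases per library, the least in control 3 and the most in Skiv2l-deleted 3. The most frequent number of bases on low genes was 78. If that is 1 read, 1 FPKM on a transcript of 1 kb stood for 22.4 to 30.7 reads. Only 40.1% to 41.1% of low values were whole multiples of that step within 0.1, so whole reads were not recovered and no count model was used. Genes at 1 FPKM or above numbered 12975 to 13738 per library.

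Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), for the 13539 genes at 1 FPKM or more in at least 3 of the 6 libraries, with the genotype as the only term. Log2 fold changes are Skiv2l-deleted minus control on this scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. Single levels and segment totals were compared by an exact two-sided permutation test of 3 against 3 values, whose smallest p is 0.1. The test was checked on simulated libraries made from the 13539 genes with their own means and spreads. It recovered 14% of the genes changed 1.5-fold, 46% of those changed 2-fold, and 90% of those changed 4-fold or 8-fold, 50 genes each, with 7 false calls among 127. Far fewer genes were changed in the simulation than the 1197 called in the real data, and recovery after adjustment depends on that share. These rates therefore need not hold for the real data. Among 40 simulated gene lists, the 1 raised list was called and 0 others were. In the real data, other splits of the 6 libraries gave 6 to 14 called lists at the preset correlation described below. The simulated lists therefore do not show how specific the list test is on these data.

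Gene lists numbered 36 and came from textbook knowledge of the SKI complex and of B cell development. They covered RNA decay, stress responses, cell cycle, B lineage stages, immunoglobulin segments, RNA quality and other bone marrow cells. For each list the members past the threshold were counted, adjusted over all genes tested and adjusted over the list alone. Members were counted as gene identifiers, so a symbol that stood on several identifiers counted for each. This concerns the glycolysis list (16 identifiers in the files) and the integrated stress response list (25). The 32 lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes, and with fry, which tests whether the members move, on balance, one way and does not compare them with other genes. Lists shared members in 5 pairs. Sesn2 stands in the p53 and the integrated stress response lists, Bbc3 and Bax in the p53 and BCL2-family lists, Bcl2 and Mcl1 in the BCL2-family and IL-7/STAT5 lists, Kit and Flt3 in the pro-B surface and progenitor lists, and Il2ra in the IL-7/STAT5 and later-stage lists.

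The lists, the tests, the rule for named genes and all alternatives except a pair named below were chosen before the data were examined. The rule named Skiv2l and Cd79a, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap (leaving out symbols of an immunoglobulin or T cell receptor locus followed by v, d, j or c, which keeps Igha and the Ighg genes in, and predicted genes, pseudogenes and genes without a symbol), and from each list up to 4 members with the smallest adjusted p, or 2 where none passed. A result under this rule is not reported here. Other genes named in the text (Igkc, Ighm, Xist, Ddx3y, Mpo, Elane, S100a9, Ltf, Hbb-bs, Tnfrsf17, Prdm1, Derl3, Cxcr5, Rag1 and Rag2) were chosen after their values were seen.

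The alternatives were 2 other pseudocounts (0.1 and 0.5), no filter, a mean of 5 FPKM or more, 3 other scalings (TPM, median of ratios, quantile), immunoglobulin segments left out, robust eBayes, array weights, the replicate number as a block, each library left out in turn, an estimated inter-gene correlation and fry. A pair of alternatives was added after seeing the data: a covariate for control 3 and Skiv2l-deleted 2, and a fit of the other 4 libraries.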

Results

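Messenger RNA was profiled in sorted bone marrow pro-B cells of 3 Skiv2l-deleted mice and 3 control mice, 1 library each. Skiv2l encodes the helicase of the SKI complex, which feeds messenger RNA into the cytosolic RNA exosome for degradation. Cd79a-Cre acts from the earliest B lineage stages, so the comparison asks what loss of Skiv2l does to the pro-B transcriptome. Libraries corresponded to 1.74 to 2.40 Gb of aligned bases. Pearson correlations of log2(FPKM + 1) were 0.951 to 0.986 within groups and 0.929 to 0.958 between groups. The first principal component, with 44.3% of the variance, separated the genotypes. The second, with 33.1%, separated control 3 and Skiv2l-deleted 2 from the other 4 libraries.

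Skiv2l itself (chromosome 17, 34839228 to 34850210, GRCm38) stood at 25.4, 20.2 and 46.3 FPKM in the controls and at 9.53, 16.1 and 10.9 FPKM in the Skiv2l-deleted libraries. Each Skiv2l-deleted library lay below each control. The means were 30.6 ± 13.8 and 12.2 ± 3.5 FPKM (SD, n = 3), a log2 fold change of −1.21 ± 0.32 (SE). That difference narrowly missed the threshold (limma adjusted p = 0.063), and the exact permutation p was 0.1, the smallest that 3 against 3 allows. Over 19 alternatives the limma adjusted p ranged from 0.00453, with a covariate for control 3 and Skiv2l-deleted 2, to 0.212, without Skiv2l-deleted 1. The floxed exons are not given in the sources used here, and reads from the rest of the gene count toward these values. Cd79a (chromosome 7, 24897381 to 24902197), which encodes the Ig-alpha signalling chain and gives the Cre driver its name, fell from 702 ± 53.8 to 392 ± 42.5 FPKM (log2 fold change −0.84 ± 0.12, limma adjusted p = 0.0123). The Cd79a call was lost without control 1 (0.0516) and without Skiv2l-deleted 1 (limma adjusted p = 0.0702). The mean of Cd79a in the Skiv2l-deleted libraries was 0.559 of that in the controls. Whether the insertion of the driver takes 1 Cd79a allele is not given in the sources used here. An effect of the driver on Cd79a therefore cannot be told apart from a response. Since the labels name Cre in the Skiv2l-deleted mice alone, every difference between the groups goes with Cre as well as with Skiv2l.

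**Figure D1:**
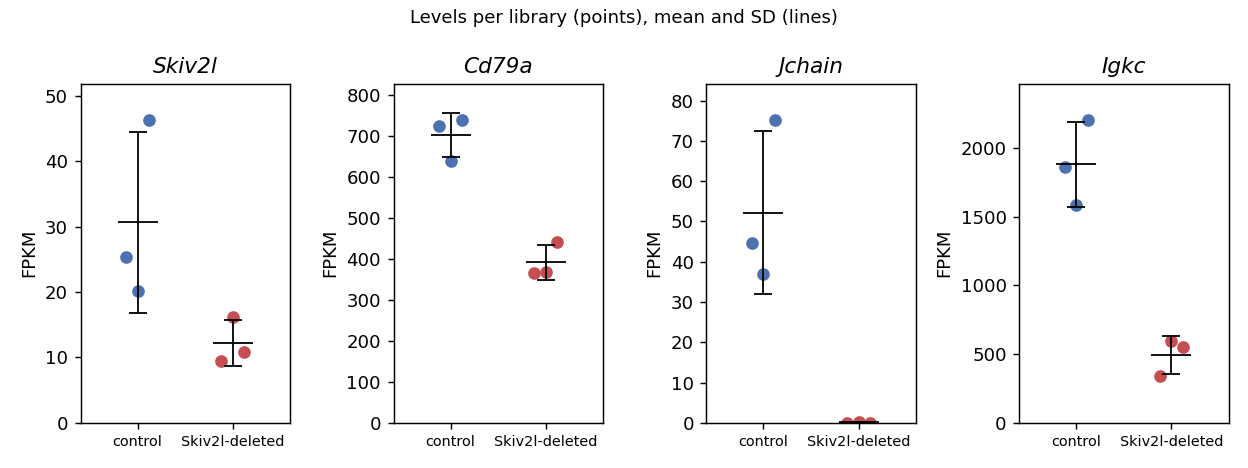
FPKM of Skiv2l, Cd79a, Jchain and Igkc (vertical axes, each from 0) in the 3 control and 3 Skiv2l-deleted libraries. Points are libraries, long lines the means and capped lines the SD. Skiv2l lies between 20.2 and 46.3 FPKM in the controls and between 9.53 and 16.1 FPKM in the Skiv2l-deleted libraries.

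Of 13539 genes tested, 1197 changed (8.84%), with 673 higher and 524 lower in Skiv2l-deleted cells, and 477 changed at least 2-fold (258 higher, 219 lower). Immunoglobulin or T cell receptor segments, by symbol, made up 117 of the 1197 and 112 of the 524 lower. With such segments left out, 916 of 13347 genes changed (537 higher, 379 lower). The groups did not overlap in 4363 genes (32.2%, where chance gives 10%), among them all 1197 that were called. The largest rises included some genes that make or transport amino acids, a grouping made after the values were seen and not tested. Asns, asparagine synthetase (chromosome 6, 7675169 to 7693254), rose from 1.5 ± 0.63 to 26.6 ± 1.68 FPKM (SD, n = 3, log2 fold change 3.49 ± 0.20, limma adjusted p = 0.0011). Slc7a3, a cationic amino acid transporter, rose by 2.07 on the log2 scale and Slc6a9, a glycine transporter, rose from 0.0738 ± 0.0677 to 3.47 ± 1.49 FPKM. The same group held the pseudokinase gene Trib3 (2.87), the transcription factor Atf5 (2.54), the glutathione-degrading enzyme Chac1 (2.11), the myosin light chain Myl10 (2.87), the protease inhibitors Serpina3f (2.69) and Serpina3g (2.47), the cytochrome oxidase subunit Cox6a2 (2.41) and the endocytic genes Ehd3 (2.20) and Ston1 (2.03). The largest falls were led by Igha, the IgA heavy chain constant gene, at 216, 164 and 380 FPKM in the controls against 0.302, 0 and 0.0845 in the Skiv2l-deleted libraries. Jchain, which links IgA and IgM into polymers, stood at 44.5, 36.9 and 75.2 against 0, 0.233 and 0.0821 FPKM. Their log2 fold changes were −7.73 for Igha and −5.53 for Jchain (limma adjusted p = 0.000202 and 0.000568). The IgG constant genes Ighg1 (−4.02), Ighg2c (−3.74) and Ighg3 (−3.03, listed at 0 in all 3 Skiv2l-deleted libraries) fell as well. The myosin light chain Myl4 (chromosome 11, 104550663 to 104595753) fell from 369 ± 8.41 to 50.7 ± 5.44 FPKM (−2.85 ± 0.11, limma adjusted p = 0.000202). Also among the largest falls were the MHC class II genes H2-Eb1 (−2.32) and H2-Aa (−2.23), the Ras activator Rasgrp1 (−2.32), the adhesion receptor Cd2 (−2.24), Myzap (−2.35) and Egfl6 (−2.06). Of these 24 genes, 22 were called in each omission of 1 library in which they passed the filter. Myzap missed the threshold without control 1, Skiv2l-deleted 1 or Skiv2l-deleted 3 (highest limma adjusted p = 0.0706), and Cd2 in each omission except that of Skiv2l-deleted 2 (highest limma adjusted p = 0.114). The count of changed genes was 381 without control 1, 475 without control 2, 184 without Skiv2l-deleted 1, 663 without Skiv2l-deleted 2 and 179 without Skiv2l-deleted 3. It was 1683 in the 4 libraries that remain without control 3 and Skiv2l-deleted 2. Serpina3f and Serpina3g, and the IgG constant genes, are close paralogs between which reads can be split.

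Among the gene lists, 14 of the 32 tested were called by camera with its preset correlation, 14 by fry and 0 with an estimated correlation (5 at an unadjusted p under 0.05), so the preset calls given below do not hold with an estimated correlation. The other 9 splits of the 6 libraries into 3 and 3 gave 6 to 14 lists with the preset correlation.

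Genes of the integrated stress response, the program that ATF4 drives when translation initiation is restrained or amino acids run short, rose as a group. Of 19 tested members, 12 rose, 0 fell and 7 did not pass (16 rose adjusted over the list alone), with a median log2 fold change of 0.91. Besides Asns, Trib3, Chac1 and Atf5, the mitochondrial serine hydroxymethyltransferase Shmt2 rose from 64.2 ± 5.69 to 148 ± 18.3 FPKM (SD, n = 3). The list was called by camera (adjusted p = 3.3e-11, against adjusted p = 0.242 with an estimated correlation) and by fry (adjusted p = 0.00477). Without Skiv2l-deleted 1 or without Skiv2l-deleted 3, 5 members rose. In the 4 libraries without control 3 and Skiv2l-deleted 2, 15 of 18 did. Of 18 ER chaperone genes of the unfolded protein response, 0 passed upward, at a median of 0.24 with 14 values above 0 (median 0.12 without control 1 and 0.06 without Skiv2l-deleted 2), and 1, the ubiquitin ligase gene Syvn1, fell (log2 fold change −0.48, limma adjusted p = 0.0451, and in 0 of 6 omissions), with 0 adjusted over the list alone, 3 members at an unadjusted limma p under 0.05 and a camera adjusted p of 0.694. Among p53 targets, 3 of 20 rose and 0 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.0921): Bbc3, which encodes the pro-apoptotic protein PUMA (1.56), Phlda3 (1.04) and the stress-induced Sesn2 (0.91). Of 14 BCL2-family and caspase genes, 3 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.129). The pro-apoptotic genes Bbc3, Bmf (0.91) and Bok (1.21) rose, and Bcl2l1, which encodes the survival protein BCL-XL, fell from 63.8 ± 4.38 to 35.8 ± 6.09 FPKM (−0.82 ± 0.14, limma adjusted p = 0.0176). Fry called both lists (adjusted p = 0.0266 for p53 targets and 0.0381 for BCL2-family and caspase genes). Glycolysis genes rose in 2 of 16 members (5 adjusted over the list alone), Hk1 (0.81) and Eno1 (0.57). That list was called by camera (adjusted p = 0.00142, against adjusted p = 0.342 with an estimated correlation). In cholesterol synthesis 1 of 24 genes, the last-step reductase gene Dhcr7 (0.68), rose (4 adjusted over the list alone, camera adjusted p = 0.138), and that list was called without control 3 (0.049), without Skiv2l-deleted 2 (0.0212) and in the 4 libraries (camera adjusted p = 0.00611). When 1 library was left out, calls were lost for Sesn2 (Skiv2l-deleted 1 or 3, highest limma adjusted p = 0.0766), Phlda3 (control 1 or Skiv2l-deleted 3, 0.0726), Bcl2l1 (control 1 or 2, Skiv2l-deleted 1 or 2, 0.086), Bmf (control 2 or any Skiv2l-deleted library, 0.14), Bok (control 1 or 2, Skiv2l-deleted 1 or 3, 0.153), Dhcr7 (control 2 or any Skiv2l-deleted library, 0.118), and Hk1 and Eno1 (any library but control 3, 0.114 and 0.144). The counts of higher p53, BCL2-family, glycolysis and cholesterol genes were 5, 5, 5 and 5 without control 3 and 1, 0, 0 and 0 without Skiv2l-deleted 1. They were 0 in each of these lists without Skiv2l-deleted 3, and the 4 libraries gave 4, 3, 5 and 7. The BCL2-family count was also 1 without control 2 or Skiv2l-deleted 2, and the glycolysis count 0 without any library but control 3.

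Genes of mitosis fell as a group. Of 33 tested G2/M genes, 21 fell and 0 rose (31 fell adjusted over the list alone), with a median log2 fold change of −0.74. Cyclin B2 (Ccnb2) fell from 199 ± 13.0 to 102 ± 2.98 FPKM (−0.96 ± 0.10, limma adjusted p = 0.00493), and Cdca3 (−1.04), Cdc25c (−0.81) and Cdca8 (−0.78) fell beside it. Camera called the list (adjusted p = 7.0e-24, against adjusted p = 0.193 with an estimated correlation), and fry gave an adjusted p of 0.00521. Of 33 G1/S and DNA replication genes, 9 fell and 0 rose, with 20 lower and 1 higher adjusted over the list alone and a median of −0.37. They included the transcription factor E2f2, from 170 ± 8.29 to 73.0 ± 9.63 FPKM, the replication factors Gins3 (−0.64) and Rfc4 (−0.56) and the ribonucleotide reductase subunit Rrm2 (−0.74). Camera called this list too (adjusted p = 3.3e-11, against adjusted p = 0.193 with an estimated correlation). Of 61 replication-dependent histone genes 1 fell, Hist3h2ba (−1.27), and 0 passed adjusted over the list alone. Their median was −0.60 (camera adjusted p = 1.2e-10, against adjusted p = 0.582 with an estimated correlation, and fry adjusted p = 0.286), and it was −0.36 without control 3 and −0.33 without Skiv2l-deleted 1. Most histone messages lack poly(A) tails, so their capture in mRNA libraries is incomplete. Fewer G2/M genes fell without control 1 (13), control 2 (12), Skiv2l-deleted 1 (3), Skiv2l-deleted 2 (11) or Skiv2l-deleted 3 (3), while in the 4 libraries without control 3 and Skiv2l-deleted 2 it was 24. For G1/S genes the omissions gave 1 or 2 members lower, except without control 3 (13), and the 4 libraries gave 12. When 1 library was left out, calls were lost for Cdc25c (Skiv2l-deleted 3, limma adjusted p = 0.052), Cdca8 (Skiv2l-deleted 1 or 3, highest 0.053), Gins3 (control 1 or 2, Skiv2l-deleted 1 or 3, 0.113), Rfc4 (control 2 or any Skiv2l-deleted library, 0.129), Rrm2 (any library but control 3, 0.109) and Hist3h2ba (control 1 or any Skiv2l-deleted library, 0.113).

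Many immunoglobulin variable segments fell. Of 100 tested Igh variable segments, 67 fell and 0 rose (85 fell adjusted over the list alone), with a median log2 fold change of −1.74. Ighv1-55 fell from 22.4 ± 1.29 to 2.11 ± 0.85 FPKM (−2.94 ± 0.20, limma adjusted p = 0.00196), and Ighv1-19 (−3.15), Ighv1-59 (−2.31) and the pseudogene segment Ighv1-62 (−2.08) fell with it. The summed FPKM of 185 Igh variable segments was 1446 ± 291 in controls and 326 ± 62.1 in Skiv2l-deleted libraries (SD, n = 3), 4.44-fold lower, with an exact permutation p of 0.1, the smallest possible. Of 76 tested Igk variable segments, 36 fell and 0 rose (60 fell adjusted over the list alone), with a median of −1.63. Igkv5-43 (−4.07), Igkv6-15 (−3.93), Igkv6-23 (−3.40) and Igkv5-45 (−2.84) were examples. The summed Igk variable segments stood at 815 ± 119 and 173 ± 49.9 FPKM. The log2 fold change was above 0 in 3 of the tested Igh and 2 of the tested Igk segments, none of which passed. Both lists were called by camera (adjusted p = 7.3e-46 for Igh and 2.0e-32 for Igk, each against adjusted p = 0.193 with an estimated correlation). The counts of lower Igh and Igk segments were 36 and 15 without control 1, 40 and 19 without control 2, 35 and 17 without Skiv2l-deleted 1, and 30 and 18 without Skiv2l-deleted 3. In the 4 libraries without control 3 and Skiv2l-deleted 2, 80 of 92 Igh and 24 of 45 Igk segments fell. Plasma cell markers moved apart. Jchain and the syndecan gene Sdc1 (−1.29, limma adjusted p = 0.0182) fell, while Mzb1, a B cell chaperone gene, rose by 0.53 at the very edge of the threshold (limma adjusted p = 0.05 when rounded). That made 2 of 4 tested members lower and 1 higher (3 and 1 adjusted over the list alone, camera adjusted p = 0.0159, against adjusted p = 0.242 with an estimated correlation). The plasma cell median was −0.84, and −0.38, −0.47 and −0.31 without control 1, 2 and 3, and its call was lost without control 1 (0.32), control 2 (0.298) or control 3 (camera adjusted p = 0.497), and in the 4 libraries (0.584). In each of these Jchain no longer passed the expression filter. Sdc1 lost its call without control 1, control 2, Skiv2l-deleted 1 or Skiv2l-deleted 3 (highest limma adjusted p = 0.0744), and Mzb1 without any library but control 3 (0.192). Variable segments are families of near-identical copies, so values of single segments are less certain than their sums.

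**Figure D2:**
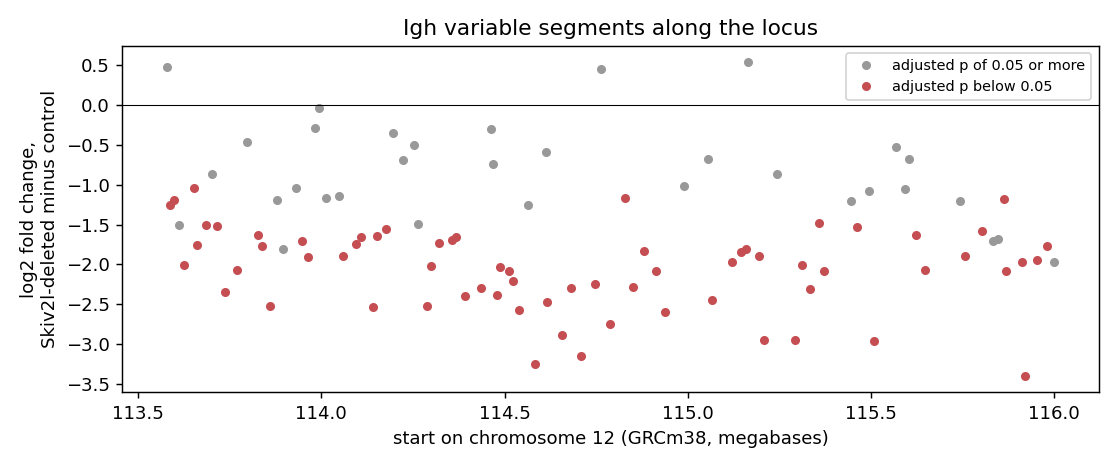
Log2 fold change of the 100 tested Igh variable segments (vertical axis) against their start on chromosome 12 (horizontal axis, megabases, GRCm38), with called segments in red and the others in grey. The segments span 113578504 to 116000461, and 67 of them were called, all below 0.

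Genes that mark successive B cell stages moved in both directions. Among 19 pro-B surface, pre-BCR and signalling genes, 7 rose and 3 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.707). Cd79a, which the Cre driver may itself lower, was among the falls. The surrogate light chain genes Igll1 (508 ± 93.7 to 1229 ± 201 FPKM) and Vpreb2 (119 ± 43.6 to 355 ± 44.2) rose, as did the surface antigen Bst1 (0.86). Of haematopoietic progenitor markers, all 3 tested rose: the receptors Kit (1.30) and Flt3 (1.34), which the pro-B list also holds, and the transcription factor Meis1 (0.71). That list of 3 was called by camera (adjusted p = 0.00926, against adjusted p = 0.283 with an estimated correlation), and 3 of 3 also rose adjusted over the list alone. Small pre-B, immature and mature B cell genes were mostly lower, with 10 of 16 falling and 2 rising (11 and 2 adjusted over the list alone) and a median of −1.19. Among the falls were the MHC class II genes, H2-Aa from 79.3 ± 8.6 to 16.5 ± 4.89 FPKM, H2-Eb1 from 35.5 ± 3.89 to 6.57 ± 2.70 and H2-Ab1 from 130 ± 16.2 to 56.2 ± 5.45 (SD, n = 3). The lymphotoxin gene Ltb went the other way, from 18.4 ± 2.96 to 63.5 ± 5.77, as did the chemokine receptor Cxcr5. Camera called this list (adjusted p = 1.4e-06, against adjusted p = 0.233 with an estimated correlation). In V(D)J recombination and end joining, 3 of 17 rose and 3 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.907). Dntt, the terminal transferase that adds nucleotides at junctions, rose from 259 ± 73.0 to 723 ± 145 FPKM, and Rag1 and Rag2 rose by 0.76 and 0.46 on the log2 scale. The DNA polymerase gene Polm (−1.91), Hmgb2 (−0.74) and Paxip1 (−0.58) fell. Of 20 early B cell transcription factors, Lef1 (0.88) and Erg (1.62) rose and Spib (−1.35) fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.694). Of 11 IL-7/STAT5 response genes 3 rose, Socs2 (1.56), Cish (1.96) and Ccnd2 (1.22), and Il2ra fell (−1.57), with 5 and 3 adjusted over the list alone and a camera adjusted p of 0.566. Omissions lowered these counts: pro-B genes rose in 2, 3 and 3 members without control 1, control 2 and Skiv2l-deleted 2, and in 0 and 1 without Skiv2l-deleted 1 and 3, while later-stage genes fell in 3, 5, 5 and 4 members without control 1, control 2, Skiv2l-deleted 1 and Skiv2l-deleted 3. In the 4 libraries without control 3 and Skiv2l-deleted 2 the pro-B list had 6 higher and 4 lower, and the later-stage list 9 lower and 2 higher of 15. When 1 library was left out, calls were lost without Skiv2l-deleted 1 or 3 for Bst1, Igll1 and Erg (highest limma adjusted p = 0.0557, 0.0618 and 0.0672), and also without control 1 for Vpreb2, Dntt and Lef1 (0.0706, 0.0728 and 0.0725). Hmgb2 lost its call without Skiv2l-deleted 1 or 3 (0.0646), Spib without control 1 or 2 or Skiv2l-deleted 1 (0.0737), Il2ra without control 1 or 2 or Skiv2l-deleted 3 (0.0766) and Polm without control 1 or 2 or Skiv2l-deleted 1 or 3 (0.105). Cish lost it without control 1 or any Skiv2l-deleted library (0.124), Ccnd2 without any library but Skiv2l-deleted 2 (0.114), Flt3 without any library but control 3 or Skiv2l-deleted 3 (0.155), and Kit, Meis1 and Paxip1 without any library but control 3 (0.142, 0.119 and 0.141). Rag1 and Rag2 passed without control 3 alone (highest limma adjusted p = 0.182 for each, without Skiv2l-deleted 1), and Cxcr5 lost its call without Skiv2l-deleted 1 (0.0749) or 3 (0.0951). V(D)J genes higher and lower numbered 0 and 1 without control 1, 1 and 1 without control 2, 1 and 2 without Skiv2l-deleted 2, and 0 and 0 without Skiv2l-deleted 1 or 3. For transcription factors these counts were 1 and 0 without control 1, 2 and 0 without control 2, 2 and 6 without control 3, 0 and 0 without Skiv2l-deleted 1, and 0 and 1 without Skiv2l-deleted 3.

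Type I interferon response genes rose in 8 of 27 members, with 0 lower (17 higher adjusted over the list alone) and a median of 0.58. The 2'-5' oligoadenylate synthetase family provided Oas3, from 2.05 ± 0.20 to 6.90 ± 1.41 FPKM (1.36 ± 0.17, limma adjusted p = 0.0084), Oas1a (1.08) and the related Oasl2 (1.19), and the interferon-induced Ifi44 rose by 1.72. Camera called the list (adjusted p = 4.2e-07, against adjusted p = 0.411 with an estimated correlation), and fry gave an adjusted p of 0.0269. Without control 1, Skiv2l-deleted 1 or Skiv2l-deleted 2, 2 members rose, without Skiv2l-deleted 3 only 1 did, and in the 4 libraries without control 3 and Skiv2l-deleted 2, 4 did. Oas3 was called in each omission, while Oas1a lost its call without any 1 Skiv2l-deleted library (highest limma adjusted p = 0.096), Ifi44 without control 1 or Skiv2l-deleted 1 or 3 (0.0973) and Oasl2 without control 1 or 2 or Skiv2l-deleted 2 or 3 (0.109). Oas1a has close paralogs with which it can share reads.

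Few genes of the RNA decay machinery around Skiv2l passed the threshold. Of 22 tested genes of the SKI complex, the cytosolic exosome and its partners, the exosome subunit Exosc3 alone passed (74.7 ± 7.46 to 52.0 ± 3.14 FPKM, −0.51 ± 0.11, limma adjusted p = 0.0387). That list holds Skiv2l itself, which did not pass (−1.21, limma adjusted p = 0.063). With the covariate for control 3 and Skiv2l-deleted 2, 3 members of the list fell and 0 rose. Exosc3 passed in 1 of 6 omissions, that of control 3 (highest limma adjusted p = 0.164 without Skiv2l-deleted 1), and 0 members passed adjusted over the list alone (2 at an unadjusted limma p under 0.05, camera adjusted p = 0.232). No nuclear exosome cofactor passed (0 of 12, also adjusted over the list alone, 3 at an unadjusted limma p under 0.05, camera adjusted p = 0.674), the nearest being Zcchc8 (−0.48, limma adjusted p = 0.0508) and Mpp6 (0.44, 0.0864). Zcchc8 passed in 1 of 6 omissions, that of control 3. It also passed in the 4 libraries without control 3 and Skiv2l-deleted 2 (limma adjusted p = 0.0437). With the covariate for that pair, Zcchc8 (0.0146) and Mpp6 (limma adjusted p = 0.0457) both passed. Nonsense-mediated decay factors gave 0 of 14, over all genes and adjusted over the list alone (1 at an unadjusted limma p under 0.05, camera adjusted p = 0.232), with Upf3b at −0.30 and Casc3 at −0.21. SnoRNA host genes, whose transcripts are known substrates of nonsense-mediated decay, gave 0 of 13 on both counts (0 at an unadjusted limma p under 0.05, camera adjusted p = 0.974), with Snhg15 at 0.71 and Snhg6 at 0.51. Without control 3 their median turned from −0.04 to 0.33, with 3 members higher and a camera call (adjusted p = 0.0223). Of 77 cytosolic ribosomal protein genes, 3 rose, among them Rps23 (0.43) and Rpl15 (0.47), with 0 adjusted over the list alone. Their median was 0.24, and camera called the list (adjusted p = 3.5e-06, against adjusted p = 0.773 with an estimated correlation, and fry adjusted p = 0.192). The ribosomal protein count was 0 in 5 of 6 omissions and 8 without control 3, and the median was 0.16 without Skiv2l-deleted 2. Of 6 tested members of the list of Skiv2l neighbours 0 passed on either count (2 at an unadjusted limma p under 0.05, camera adjusted p = 0.81), with C2 at 0.54 and Zbtb12 at 0.55. That list does not cover all genes near Skiv2l. Also on chromosome 17, the called genes H2-Ab1, H2-Aa and H2-Eb1 (starts 34263209, 34282744 and 34305877) were lower and Ltb (35194439) was higher. Whether calls cluster around Skiv2l was not tested. Medians, means and tests differed in sign for the SKI complex, nuclear exosome, snoRNA host, V(D)J recombination, transcription factor, immediate early, neutrophil and monocyte lists, each within 0.25 of 0 in median.

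**Figure D3:**
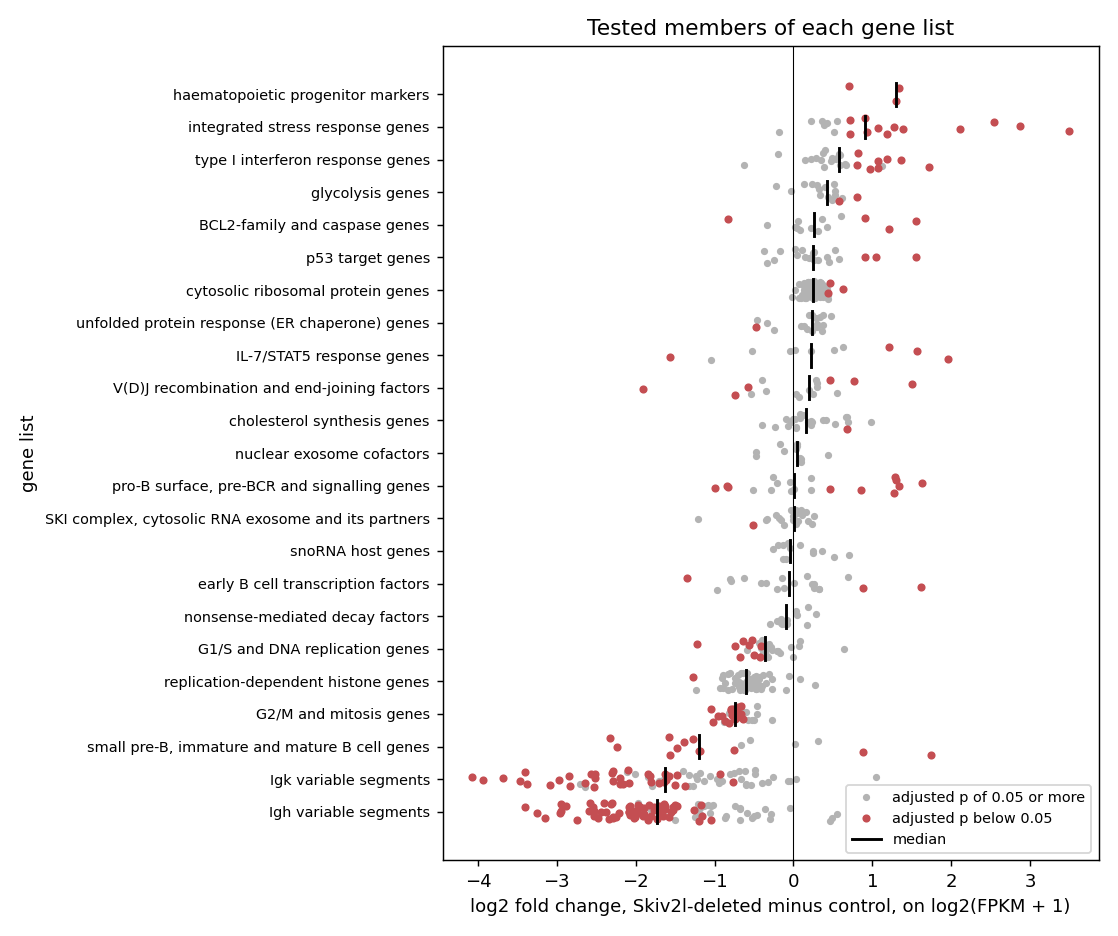
Log2 fold change on log2(FPKM + 1) (horizontal axis) of each tested member of the pathway, segment, later-stage and progenitor lists (vertical axis, ordered by median). Red points passed adjusted p below 0.05, grey points did not, and black bars are list medians, which run from −1.74 for Igh variable segments to 1.30 for haematopoietic progenitor markers.

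Control 3 and Skiv2l-deleted 2 differed from the other libraries in sex-linked and granulocyte precursor transcripts, 1 such library in each group. Xist, expressed from the inactive X chromosome, stood at 131 and 70.1 FPKM in them and at 0.113 or less in the other 4 libraries, while the Y-linked Ddx3y stood at 0.0388 and 0.00849 against 13.8 to 21.8. The granule protein gene Mpo stood at 343 and 641 FPKM against 4.30 to 8.99 in the others, and Elane at 168 and 341 against 2.02 to 3.95. Mature neutrophil transcripts were not limited to this pair. The calcium-binding protein gene S100a9 stood at 217 and 177 FPKM in control 2 and 3 and at 165 and 243 in Skiv2l-deleted 1 and 2, against 1.5 in control 1 and 1.98 in Skiv2l-deleted 3. The granule protein gene Ltf was highest in control 2 (18.5) and Skiv2l-deleted 1 (15.8), at 2.84 and 2.74 in control 3 and Skiv2l-deleted 2, and listed at 0 in control 1 and Skiv2l-deleted 3. Skiv2l-deleted 2 also held the haemoglobin gene Hbb-bs at 47.5 FPKM, against 0.338 to 1.95 in the other 5 libraries. Neutrophil and granulocyte precursor markers gave 0 of 11 past the threshold (camera adjusted p = 0.81), with Retnlg at 0.35 and Ctsg at 0.27. Monocyte and macrophage markers gave 0 of 4 (camera adjusted p = 0.81), with Lyz2 at 0.11 and Ly6c2 at −0.11, and basophil and mast cell markers 0 of 2, too few for a list test, with Prss34 at −0.45 and Mcpt8 at −0.43. These values turned sign with 1 library: the neutrophil median ran from −1.13 without Skiv2l-deleted 2 to 1.34 without Skiv2l-deleted 3 and was also negative without control 1 (−1.12) or Skiv2l-deleted 1 (−0.56), and the monocyte median ran from −1.28 without Skiv2l-deleted 2 to 0.97 without control 3. In all 3 lists 0 members passed adjusted over the list alone or at an unadjusted limma p under 0.05. Erythroid markers had 1 of 6 higher, the carbonic anhydrase gene Car2 (0.63, 1 adjusted over the list alone, camera adjusted p = 0.22), which passed in 1 of 6 omissions, that of control 3 (highest limma adjusted p = 0.0993). The erythroid list was called without Skiv2l-deleted 3 (camera adjusted p = 0.019). Among T cell markers Thy1 (1.32) rose, 1 of 3 tested (3 adjusted over the list alone, camera adjusted p = 0.0159, against adjusted p = 0.342 with an estimated correlation), and Thy1 lost its call without Skiv2l-deleted 1 or 3 (highest limma adjusted p = 0.0563). Among NK and innate lymphoid markers Klrb1c (1.65) rose, 1 of 4 (1 adjusted over the list alone, camera adjusted p = 0.472). Among plasmacytoid dendritic cell markers Cox6a2 rose, 1 of 3 (2 adjusted over the list alone, camera adjusted p = 0.0288, against adjusted p = 0.262 with an estimated correlation and 0.067 without control 3). Only 3 of 11 T cell markers, 4 of 11 NK and innate lymphoid markers and 3 of 7 plasmacytoid dendritic cell markers passed the expression filter. These lists therefore say little about RNA of those cells. Megakaryocyte, stromal and mitochondrially encoded lists had 0 members past the expression filter. Immediate early and handling stress genes gave 0 of 14 on both counts (3 at an unadjusted limma p under 0.05, camera adjusted p = 0.566), with Nfkbia at −0.75 (limma adjusted p = 0.0684) and Ier2 at 0.73.

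**Figure D4:**
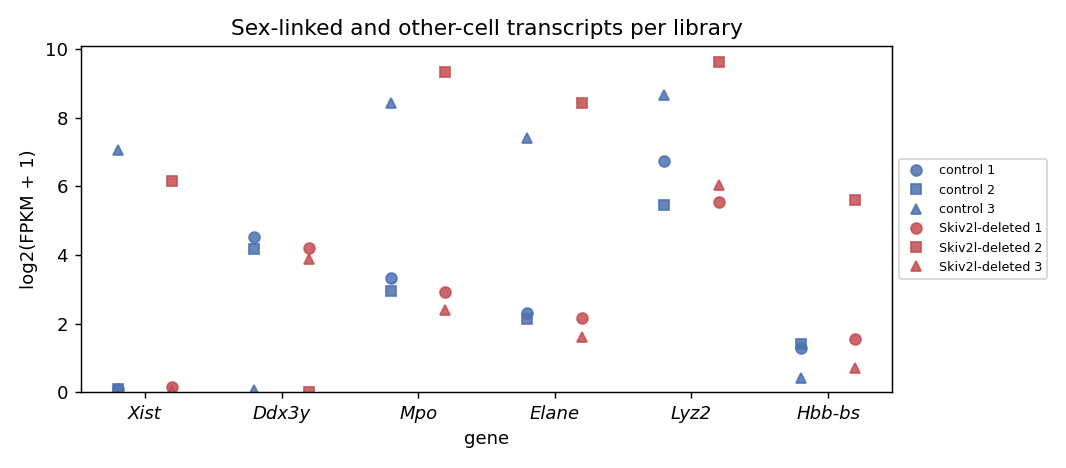
Log2(FPKM + 1) (vertical axis) of Xist, Ddx3y, Mpo, Elane, Lyz2 and Hbb-bs (horizontal axis) in each library, with controls in blue, Skiv2l-deleted libraries in red and symbols for the replicates. Control 3 and Skiv2l-deleted 2 stand apart, with Xist at 131 and 70.1 FPKM.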

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

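The covariate for control 3 and Skiv2l-deleted 2 and the fit of the other 4 libraries were chosen after the result was seen; the other settings were planned, and those planned for read counts were not run because the tables hold none. Main counts were 1197 changed genes, 673 higher, 524 lower and 477 at least 2-fold. Without a filter, with 28354 genes tested in place of 13539, they were 512, 280, 232 and 224. Array weights gave 3449, 2042 and 1407, and the covariate gave 2620, 1591 and 1029. Leaving out 1 library gave 179 to 1749 changed genes, 63 to 1020 higher, 113 to 729 lower and 172 to 583 at least 2-fold. Apart from fewer genes or libraries, the cause was not tested. Pseudocounts, stricter filter, scalings and robust eBayes gave 912 to 1216 changed genes, and 1000 to 1191 calls were shared with the main result where all 13539 genes were kept. The share of higher genes was 56.2%, and it was 48.0% after quantile normalization, 38.6% without Skiv2l-deleted 1 and 35.2% without Skiv2l-deleted 3.

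The Skiv2l difference passed at −1.24 with TPM scaling (adjusted p = 0.0439), −1.26 with median of ratios (0.0499), −1.24 with quantile normalization (0.048), −1.22 without immunoglobulin segments (0.046), −1.13 with array weights (0.00562), −1.21 with the covariate (0.00453) and −1.08 in the 4 libraries (0.0172), within a limma adjusted p of 0.00453 to 0.212 over 19 settings. The Cd79a difference of −0.84 missed the threshold without a filter (0.0527), and its value lay between −0.93 and −0.80 when 1 library was left out (highest limma adjusted p = 0.0702). The Igh variable segment total kept its direction in the 9 alternatives run for it (a segment filter, median of ratios, 6 omissions and the 4 libraries), from −2.35 to −2.01 on the log2 scale.

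With the replicate number as a block, 365 genes changed (185 higher, 180 lower), and Cd79a stayed at −0.84 with a limma adjusted p of 0.0504. The labels do not pair the libraries. Deviations of same-numbered libraries correlated at 0.09, −0.43 and −0.35, and 0 libraries correlated best with their own number. Control 1 correlated best with Skiv2l-deleted 3 (0.41), control 2 with Skiv2l-deleted 1 (0.49) and control 3 with Skiv2l-deleted 2 (0.56), and no fit used these matches as a block.

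Of 14 called lists, 0 were called with an estimated correlation. Over 100 named genes, 1531 of 1818 settings kept the side of the threshold, 256 lost the call, 31 gained it, and 0 turned the direction of a gene called in either fit. Over 32 lists it was 635, 22, 8 and 1 of 666. The turn was that of snoRNA host genes, whose median was 0.33 without control 3 (camera adjusted p = 0.0223), within −0.18 to 0.33 when 1 library was left out. Genes and lists called in neither fit also turned sign, such as neutrophil (median −1.13 to 1.34) and monocyte markers (−1.28 to 0.97). Of simulated 2-fold changes, 46% were recovered.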

Other observations

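Within the immunoglobulin loci, segments did not all move the same way. Of 11 tested Igh diversity segments, which are transcribed before and during the first joining step, 5 rose and 0 fell. Their summed FPKM was 22.1 ± 2.60 in controls and 47.6 ± 12.8 in Skiv2l-deleted libraries (SD, n = 3, exact permutation p = 0.1, the smallest possible). Of 12 tested joining segments, 8 fell and 0 rose, and the 4 Igh joining segments summed to 1052 ± 195 and 434 ± 26.1 FPKM. Of 11 tested constant genes, 7 fell and 0 rose. Igkc, the kappa constant gene, stood at 1882 ± 311 and 495 ± 136 FPKM, 3.81-fold lower, and Ighm, the IgM heavy chain gene, at 3402 ± 187 and 2234 ± 138, 1.52-fold lower, each with an exact permutation p of 0.1. The limma call of Ighm was kept without control 3 alone when 1 library was left out (highest adjusted p = 0.153, without Skiv2l-deleted 1).

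The predictions for distance along the locus, for the 4 libraries and for the splits were written before their values were computed, and the other tests below were chosen after the result was seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1197 changed genes, 673 higher, 524 lower and 477 at least 2-fold, each the most in 1 of the 10 splits, with 1 as the highest other count of each. For gene lists, 2 of the 10 splits gave as many as the real 14, and the highest other was 14, with control 1, Skiv2l-deleted 1 and Skiv2l-deleted 3 on one side.

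Igha, IgG and Jchain transcripts were among the largest falls. The authors' normalization is argued against, since Jchain kept a log2 fold change of −5.53 or lower under 3 other scalings. RNA of plasma cells in the control sorts may be the source of these transcripts, and whether it is cannot be told apart from a change within the sorted cells. The other tested plasma cell markers had a median of −0.39, and Tnfrsf17 stood at 0.348, 0.397 and 0.538 FPKM in controls and was listed at 0 in all Skiv2l-deleted libraries, but Prdm1 overlapped between groups and Mzb1 rose. Of the 6 markers, 3 (Sdc1, Mzb1 and Derl3) are expressed by all 6 libraries and so say little, and the median of −0.39 rests on these 3. The surface markers of the sort are not given, so whether it removes plasma cells is not known.

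The fall of Igh variable segments likewise did not come from scaling, since their median stayed at −1.77 or lower under 3 other scalings. Fewer cells past the pro-B stage in the sorted Skiv2l-deleted population may account for it, as a hypothesis. The later-stage genes had a median log2 fold change of −1.19 and the progenitor markers one of 1.30, although Ltb and Cxcr5 rose against that direction. RNA of plasma cells in the control sorts, named above for Igha and Jchain, could also raise variable segments in the controls. It was not tested for these segments and stays open. Reduced joining of distal segments, which would lower segments more with distance from the diversity segments, stays open. Across the 100 segments, which are not independent replicates, Spearman's rho was −0.19 and Pearson's r −0.17 (permutation p = 0.0574 for rho, 100000 resamples), with medians of −1.52 among the nearest segments and −1.83 among the farthest.

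The rise of integrated stress response genes had a median of 0.91. Immediate early genes stood at a median of 0.056 (SD of members 0.46, median −0.14 to 0.18 when 1 library was left out). This argues against handling or sorting stress that raises those genes as the whole cause. The ER chaperone genes stood at a median of 0.24 (SD 0.30, median 0.0577 to 0.331 when 1 library was left out). They did not rise by as much as the integrated stress response genes. ER stress stays open, because chaperone genes do not report a part of it that acts through the integrated stress response. Control 3 and Skiv2l-deleted 2 are argued against as the source of the integrated stress response rise. The list median was 0.92 in the other 4 libraries. A part for neutrophil RNA, which control 2 and Skiv2l-deleted 1 also hold, stays open. A response to loss of Skiv2l may underlie the rise, as a hypothesis drawn from these same data and not tested. Cre, named in the same mice alone per the labels, was not tested and remains open.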
